A study of Mus musculus with 5 samples.

How the data were processed

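Bone marrow cells of wild type and NICcA mice, 7 to 8 weeks old, were cultured with 25 ng/ml M-CSF for 7 days, and RNA of the resulting macrophages was sequenced on an Illumina instrument, per the labels' protocols. Of the 5 libraries, 3 are wild type and 2 are NICcA, grouped by the genotype in the labels. The submitters' processing notes name Bowtie 0.12.2 and the mouse build mm8, without saying what each was used for. The counting tool, its strand setting and its filters are not given in the sources used here. The reference annotation at hand is of another build, so no coordinates are given.

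The first deposited table holds, per the file headers and the series' design text, the authors' raw read count and RPKM (read counts scaled to transcript length and library size) for 27457 RefSeq transcript rows of 20583 gene symbols. The second deposited table holds RPKM values alone, for 64528 rows: 27456 RefSeq mRNAs, 3719 noncoding RefSeq transcripts and 33353 FANTOM cDNA clones. For the 27456 rows in both tables, 6 RPKM values differed by more than a relative tolerance of 1e-05. Isoform rows of a gene share reads in these counts: in the 2542 genes with 2 or more rows at a mean count of at least 100, the other rows carried a median of 96.7% of the count of the top row. In 47 rows the symbol had been turned into a date, and all but 1 were renamed by their RefSeq accession. Paralogs can share reads, and 22 genes at a mean count above 10 had counts identical to those of another symbol.

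Rows were tested as given, and each gene is represented by its row with the highest mean count, in counts of genes and in gene lists. The plan named genes where the file holds transcript rows. Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr, glmQLFit and glmQLFTest with default settings, genotype as the only term, and Benjamini-Hochberg adjustment over 18267 rows (13341 genes) at an adjusted p below 0.05. Standard errors are the absolute log2 fold change divided by the square root of the quasi-likelihood F. CPM values are counts scaled to 1e6 per TMM-scaled library, and the SD is over libraries. The common biological coefficient of variation was 22.5%. In simulated libraries of the same sizes, with 50 genes changed at each fold, edgeR recovered 58% of 2-fold, 98% of 4-fold, 100% of 8-fold and 100% of 16-fold changes over 13341 genes. The changed genes had a mean of at least 1 CPM, and noise was drawn independently per gene from edgeR's own dispersion estimates. These shares need not hold in the data, where Ccl24 had a log2 fold change of 6.81 (SE 0.82) and did not pass (edgeR adjusted p = 0.22).

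Gene lists (32, written before the data were examined) covered the Notch pathway, macrophage activation, antigen presentation, lysosomes, metabolism, cell cycle, matrix factors, stress, sex and markers of other cell types. The 31 lists with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), with an estimated correlation and fry beside it, adjusted over the lists, and principal components were taken from the same values, centred per gene. Camera asks whether a list stands apart from other genes. Fry asks whether its members move in a common direction, or in either direction, without comparing them with other genes. With an estimated correlation, camera also takes its degrees of freedom from the few libraries rather than from the many genes. The second table was tested with limma (eBayes with trend) on log2(RPKM + 1) for transcripts with an RPKM of at least 1 in at least 2 libraries.

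Named genes followed a rule fixed before the data were examined: the 10 largest rises and falls among genes past the threshold at a mean of at least 5 CPM or, with fewer than 10 such genes, the 10 with the smallest p; of each list up to 4 members past the threshold or else the 2 with the smallest p; and Notch1, Hes1, Hey1, Dtx1, Nrarp, Lyz2, Actb and Gapdh always. A gene named outside the rule was chosen after its values were seen, and 1 gene that the rule takes is not reported here. Alternatives were RLE, upper-quartile or no scaling factors, other low-count filters, DESeq2 1.42.0, limma-voom, other edgeR settings, limma on RPKM, the replicate number as a term, and each library left out in turn. Figures and further tests used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.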

Results

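Messenger RNA was sequenced from mouse bone marrow-derived macrophages, the adherent phagocytes that grow out of bone marrow cells cultured with the growth factor M-CSF. Cultures came from C57BL/6 background mice of 2 genotypes, wild type (n = 3 libraries) and NICcA (n = 2 libraries, numbered 2 and 3). The labels do not spell NICcA out. In earlier use, the name stands for mice in which the intracellular domain of a Notch receptor, the part that enters the nucleus and activates transcription together with Rbpj, is conditionally expressed. Total counts over all transcript rows were 57442309, 76562905 and 69140350 for wild type replicates 1, 2 and 3, and 64870248 and 68110891 for NICcA replicates 2 and 3. The number of genes at a count of 0 was 5254, 5240 and 2364 in the wild type libraries and 4951 and 3260 in the NICcA libraries. The 10 most abundant genes held 12.0%, 12.7% and 13.3% of the counts in wild type and 9.3% and 10% in NICcA. The labels do not say that libraries of a group came from separate animals or cultures, so p-values measure the spread between these libraries, which may be technical.

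The first question is which genes differ between NICcA and wild type macrophages. Adamdec1, a secreted metalloprotease-like protein made by macrophages and dendritic cells, rose from 0.0981 ± 0.0207 to 9.28 ± 2.8 CPM (counts scaled to library size; mean ± SD, n = 3 wild type and n = 2 NICcA here and throughout). Apol7c, an apolipoprotein L family member, rose from 3.47 ± 0.84 to 64.0 ± 4.91 CPM. Mmp9, the gelatinase that degrades type IV collagen, rose from 1.02 ± 0.264 to 21.7 ± 1.06 CPM. Mpzl2, an adhesion protein of the immunoglobulin superfamily, rose from 0.461 ± 0.119 to 9.04 ± 2.89 CPM. These 4 genes rose and 0 fell among 13341 genes tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment.

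The log2 fold change was 6.55 (SE 0.31, adjusted p = 0.0067) for Adamdec1, 4.20 (SE 0.21, adjusted p = 0.0067) for Apol7c, 4.41 (SE 0.23, adjusted p = 0.0067) for Mmp9 and 4.30 (SE 0.32, adjusted p = 0.045) for Mpzl2. Each was higher in 2 of 2 NICcA libraries than in any wild type library, and each changed by more than 2-fold. A further 6 genes completed the 10 with the smallest p without passing edgeR's adjustment, while DESeq2 called all 6 among its 527 genes. The edgeR setting legacy = FALSE, chosen after seeing the data, called Tlr12, Tspan15 and Hes1 (adjusted p = 0.048 for each). Tlr12, a Toll-like receptor, had a log2 fold change of 2.61 (SE 0.22, adjusted p = 0.064). The tetraspanin genes Tspan13 and Tspan15 had log2 fold changes of 2.83 (SE 0.28) and 5.29 (SE 0.55), both at an adjusted p of 0.13. Dio2, which encodes a thyroid hormone deiodinase, was at 12.5 ± 2.13 CPM in wild type and 2.87 ± 0.104 CPM in NICcA (log2 fold change -2.12, SE 0.20, adjusted p = 0.11). Fos, a subunit of the transcription factor AP-1, was at 28.2 ± 1.81 and 13.3 ± 0.379 CPM (log2 fold change -1.08, SE 0.11, adjusted p = 0.13). Hes1, a repressor switched on directly by Notch signalling, was at 0.0589 ± 0.0377 CPM in wild type and 2.25 ± 0.731 CPM in NICcA (log2 fold change 5.18, SE 0.54, adjusted p = 0.13), from counts of 1, 5 and 6 against 185 and 125.

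**Figure D1:**
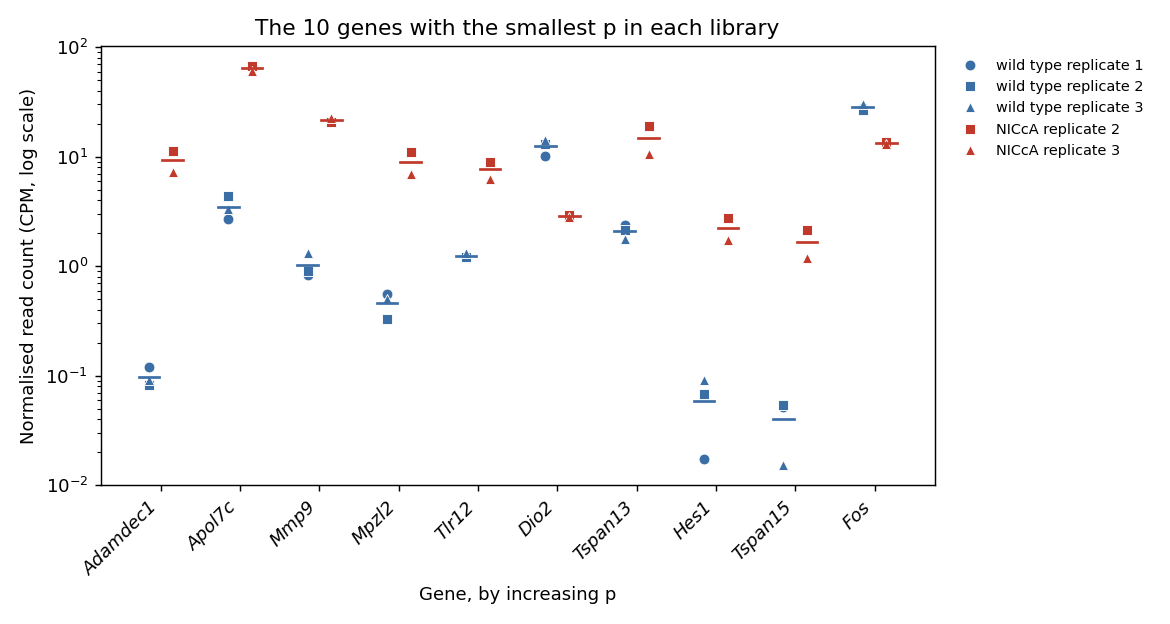
Normalised read count in CPM on a log axis for the 10 genes with the smallest p, in the order of p; points are libraries, with wild type in blue and NICcA in red, and horizontal lines are group means. Apol7c sits at 2.72, 4.38 and 3.31 CPM in the wild type libraries and at 67.5 and 60.6 CPM in the NICcA libraries, and for each of the 10 genes both NICcA libraries lie on the same side of the 3 wild type libraries.

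Beyond these genes, 1936 genes had an unadjusted p below 0.05, 1025 of them with higher and 911 with lower values in NICcA. Both NICcA libraries lay on the same side of all wild type libraries for 4913 genes, 36.8% of those tested. A random split into groups of these sizes gives 20% on average. Genes vary together, so a split along an axis that many genes share can exceed that without an effect of genotype. On the first principal component of log2 CPM (55.7% of the variance), wild type replicates 1, 2 and 3 lay at -1.1, -18.9 and -57.9 and NICcA replicates 2 and 3 at 53.7 and 24.1, so wild type replicate 3 stood farther from wild type replicate 1 than NICcA replicate 3 did. DESeq2, the other count test, called 527 genes, 273 higher and 254 lower. In simulated libraries of the same sizes it called 85 of 13141 unchanged genes where edgeR called 12. Simulated genes varied independently, so these numbers do not give the share of false calls in the data. All 4 edgeR calls were lost without wild type replicate 2 (adjusted p of 0.25 for Adamdec1, 0.068 for Apol7c, 0.25 for Mmp9 and 0.4 for Mpzl2) or without NICcA replicate 2 (0.068 for Adamdec1, Apol7c and Mmp9 and 0.23 for Mpzl2), the call on Mpzl2 also without wild type replicate 1 (0.09) or 3 (0.078), and without NICcA replicate 3 edgeR called 44 genes. Without wild type replicate 2 and without NICcA replicate 2 the log2 fold changes stayed large. They were 6.43 (SE 0.39) and 6.20 (SE 0.32) for Adamdec1 and 4.41 (SE 0.16) and 4.12 (SE 0.26) for Apol7c. For Mmp9 they were 4.33 (SE 0.28) and 4.46 (SE 0.28), and for Mpzl2 4.09 (SE 0.33) and 3.92 (SE 0.34). Among the fits without 1 wild type library, the unadjusted p of Adamdec1, Mmp9 and Mpzl2 was highest without replicate 2. That of Apol7c was higher without wild type replicate 3, where its call stayed. A higher unadjusted p on fewer libraries therefore does not account for every lost call, and the cause was not tested. Over the alternatives, the adjusted p of these 4 genes ranged from 1.5e-67 to 0.4.

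Genes of the Notch pathway come first among the gene lists fixed before the data were examined. Canonical Notch target genes stood higher in NICcA as a group, with a median log2 fold change of 0.60 over 13 measured members. The list passed limma's camera test with its preset correlation (adjusted p = 0.0048) and did not with an estimated one (adjusted p = 0.55 with an estimated correlation). Nor did it pass fry's test of a common direction (adjusted p = 0.099). Its estimated correlation was -0.015, below the preset 0.01, so correlation between members does not account for the loss under camera. Hes1 led the list. Bcl2, which blocks cell death, was at 6.94 ± 0.53 CPM in wild type and 15.8 ± 3.07 CPM in NICcA (log2 fold change 1.18, SE 0.17, adjusted p = 0.27). Nrarp, a feedback inhibitor of Notch signalling, was at 0.151 ± 0.0889 and 0.729 ± 0.0697 CPM (log2 fold change 2.24, SE 0.54, adjusted p = 0.28).

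Of the 13 members, 0 passed edgeR's adjustment over all genes and 5 were higher when adjusted over the list alone; here and below, both counts are edgeR's and those of DESeq2, over all genes, are named as such. Those 5 were Hes1, Bcl2, Nrarp, Myc and Ccnd1, and DESeq2 called 4 members higher. Myc was at 8.35 ± 0.286 and 12.7 ± 1.22 CPM, and Ccnd1, a cyclin of the G1 phase, was at 7.99 ± 4.98 and 39.3 ± 6.06 CPM. Here and below, a list member outside the rule for named genes was chosen after its values were seen. Hey1 and Dtx1, also Notch targets, had log2 fold changes of -1.11 (SE 0.57, adjusted p = 0.40) and 0.88 (SE 0.86, adjusted p = 0.64).

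The receptors, ligands and other components of the Notch pathway did not stand apart from other genes (camera adjusted p = 0.85), with 0 of 24 members past edgeR's threshold over all genes and 0 when adjusted over the list alone, while DESeq2 called 1 higher. Their median log2 fold change was -0.04 and their mean 0.16. Notch1, the receptor whose intracellular domain the genotype's name recalls, was at 78.5, 68.1 and 67.4 CPM in wild type replicates 1, 2 and 3 and at 84.2 and 87.6 CPM in NICcA replicates 2 and 3 (log2 fold change 0.27, SE 0.11, adjusted p = 0.34). A transcript made from an inserted cassette is counted with Notch1 only as far as it shares that sequence. Maml3, a coactivator of the Notch complex, had a log2 fold change of 0.69 (SE 0.19, adjusted p = 0.29; 0.047 with DESeq2), and the ligand gene Dll1 one of 1.02 (SE 0.33, adjusted p = 0.31).

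Genes of classical (M1) activation, the state macrophages enter on bacterial products and interferon gamma, stood higher in NICcA as a group, with a median log2 fold change of 2.28 and 23 of 23 measured members at a positive value. The group passed camera (adjusted p = 1.8e-07; adjusted p = 0.61 with an estimated correlation), with 0 members past edgeR's threshold over all genes and 14 higher when adjusted over the list alone, and DESeq2 called 6 members higher. Il1b, which encodes interleukin-1 beta, was at 16.6, 14.3 and 14.8 CPM in wild type and at 501 CPM in NICcA replicate 2 and 76.4 CPM in NICcA replicate 3 (log2 fold change 4.24, SE 0.72, adjusted p = 0.27). Il12a, a subunit of interleukin-12, was at 0.0313 ± 0.0162 CPM in wild type and 2.78 ± 2.03 CPM in NICcA (log2 fold change 6.42, SE 0.70, adjusted p = 0.15). The median difference from the wild type mean was 3.1 on the log2 scale in NICcA replicate 2 and 0.39 in NICcA replicate 3, where the wild type libraries spanned -0.38 to 0.30.

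Interferon-stimulated genes were high in 1 of the 2 NICcA libraries. Their median difference from the wild type mean was 2.0 on the log2 scale in NICcA replicate 2 and -0.078 in NICcA replicate 3, while the wild type libraries spanned -0.30 to 0.17. Ifi44 was at 1.34, 1.41 and 0.561 CPM in wild type and at 28.8 and 1.37 CPM in NICcA replicates 2 and 3 (log2 fold change 3.77, SE 1.12, adjusted p = 0.30). Phf11b was at 2.57 ± 0.565 CPM in wild type and at 28.8 and 3.56 CPM in the NICcA libraries (log2 fold change 2.65, SE 0.77, adjusted p = 0.29). The list passed camera (adjusted p = 7.1e-05; adjusted p = 0.82 with an estimated correlation), and without NICcA replicate 2 its direction turned (adjusted p = 0.14). Of its 30 members, 0 passed over all genes with edgeR, 0 when adjusted over the list alone and 0 with DESeq2.

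NF-kB targets and feedback regulators and MHC class I presentation genes followed the same libraries. Their medians were 0.87 and 0.88 on the log2 scale in NICcA replicate 2 and -0.077 and -0.08 in NICcA replicate 3. Socs1, an inhibitor of cytokine signalling, was at 8.32 ± 3.31 CPM in wild type and at 61.4 and 17.7 CPM in the NICcA libraries (log2 fold change 2.25, SE 0.57, adjusted p = 0.28). Nfkbie, an inhibitor of NF-kB, had a log2 fold change of 1.03 (SE 0.30, adjusted p = 0.29). Psmb8, an immunoproteasome subunit, and Tap2, a peptide transporter, had log2 fold changes of 0.78 (SE 0.23, adjusted p = 0.29) and 0.82 (SE 0.25, adjusted p = 0.30).

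The NF-kB list passed camera in the upward direction (adjusted p = 0.019; adjusted p = 0.82 with an estimated correlation), as did the MHC class I list (adjusted p = 0.033; adjusted p = 0.82 with an estimated correlation). Of 24 and 18 members, 0 passed over all genes with edgeR and 0 when adjusted over the list alone in either list, while DESeq2 called 2 NF-kB members higher and, of MHC class I, 1 higher and 1 lower. Without NICcA replicate 2 both turned direction (adjusted p = 0.37 and 0.82), without wild type replicate 1 both calls ended (0.2 and 0.17), and the MHC class I call also ended without wild type replicate 3 (0.071). Chemokines and their receptors did not stand apart (camera adjusted p = 0.85, 0 of 19 members over all genes with edgeR or DESeq2 and 0 when adjusted over the list alone, median log2 fold change -0.08 and mean 0.47). Ccl12 had a log2 fold change of 1.60 (SE 0.65, adjusted p = 0.34).

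Genes of MHC class II presentation, which loads peptides for CD4 T cells, stood higher as a group with a median log2 fold change of 0.23 over 13 members. Camera called the list (adjusted p = 0.024; adjusted p = 0.61 with an estimated correlation). Ciita, the master activator of these genes, was at 172 ± 25.0 CPM in wild type and 306 ± 5.96 CPM in NICcA (log2 fold change 0.83, SE 0.15, adjusted p = 0.27), and it alone was higher when adjusted over the list alone, while 0 members passed over all genes with edgeR, and DESeq2 called 2 higher and 1 lower. Ctss, the protease cathepsin S, went the other way, at 6900 ± 1650 and 3870 ± 423 CPM (log2 fold change -0.83, SE 0.24, adjusted p = 0.29). The call ended without wild type replicate 1 (0.2), NICcA replicate 2 (0.076) or NICcA replicate 3 (0.083). Dendritic cell markers, from cells rich in MHC class II, had a median log2 fold change of 1.13, with list medians of 1.4 and 0.79 on the log2 scale in NICcA replicates 2 and 3.

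Genes of alternative (M2) activation went both ways and did not stand apart as a group (camera adjusted p = 0.83). Ccl24, an eosinophil-attracting chemokine, was at 1.02, 0.123 and 0.319 CPM in wild type and at 76.8 and 29.0 CPM in NICcA (log2 fold change 6.81, SE 0.82, adjusted p = 0.22). Chi3l3, a secreted chitinase-like protein also known as Ym1, was among the most abundant transcripts, at 15000 ± 2400 CPM in wild type and 4740 ± 1250 CPM in NICcA (log2 fold change -1.67, SE 0.25, adjusted p = 0.27). Its relative Chi3l4 was at 4.14 ± 0.536 and 0.936 ± 0.224 CPM (log2 fold change -2.14, SE 0.26, adjusted p = 0.22), and these paralogs can share reads. Of 25 members, 0 passed over all genes with edgeR, and DESeq2 called 2 higher and 4 lower. When adjusted over the list alone, Ccl24 and Socs2 were higher and Chi3l3, Chi3l4, Retnla and Pparg were lower. The median log2 fold change was 0.41 and the mean 0.36, while fry's test of a common direction gave the downward one (adjusted p = 0.71).

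Lysosomal genes stood lower in NICcA as a group, with 30 of 33 members at a negative log2 fold change and a median of -0.40. The list passed camera (adjusted p = 1.4e-08; adjusted p = 0.61 with an estimated correlation), with 0 members past edgeR's threshold over all genes and 1, Atp6v0d2, lower when adjusted over the list alone, and DESeq2 called 8 members lower. The list medians were -0.41 and -0.37 on the log2 scale in NICcA replicates 2 and 3 and -0.15, 0.0065 and 0.13 in wild type replicates 1, 2 and 3. Atp6v0d2, a subunit of the proton pump that acidifies the lysosome, was at 573 ± 74.7 CPM in wild type and 325 ± 9.01 CPM in NICcA (log2 fold change -0.82, SE 0.15, adjusted p = 0.27). Ctsh, the protease cathepsin H, was at 418 ± 24.6 and 306 ± 0.853 CPM (log2 fold change -0.45, SE 0.11, adjusted p = 0.28).

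LXR targets and lipid-handling genes also stood lower as a group, with a median log2 fold change of -0.53 over 20 members. Camera called these genes (adjusted p = 0.0048; adjusted p = 0.61 with an estimated correlation), and the call ended without NICcA replicate 3 (0.078). Fabp4, a fatty acid binding protein, was at 39.8 ± 10.4 CPM in wild type and 17.9 ± 3.15 CPM in NICcA (log2 fold change -1.15, SE 0.26, adjusted p = 0.27). Fasn, the fatty acid synthase, went the other way (log2 fold change 0.82, SE 0.18, adjusted p = 0.27). When adjusted over the list alone, Fasn was higher and Fabp4, Apoc1, Pltp and Plin2 were lower, and 0 passed over all genes with edgeR, where DESeq2 called 1 higher and 3 lower.

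Phagocytic and scavenger receptors stood lower as a group, with a median log2 fold change of -0.28 and a mean of -0.09 over 31 members. Camera called the receptors (adjusted p = 0.021; adjusted p = 0.55 with an estimated correlation), and the call ended without NICcA replicate 3 (0.34) and without both libraries numbered 3 (0.41). Tlr7, which senses single-stranded RNA, was at 223 ± 24.6 CPM in wild type and 136 ± 11.2 CPM in NICcA (log2 fold change -0.71, SE 0.14, adjusted p = 0.27). Trem2, a receptor for lipids, was at 201 ± 17.4 and 118 ± 23 CPM (log2 fold change -0.78, SE 0.16, adjusted p = 0.27). These genes and Colec12 were lower when adjusted over the list alone, and 0 passed over all genes with edgeR, where DESeq2 called 1 higher and 4 lower.

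Cell cycle and DNA replication genes stood higher in NICcA as a group, with 35 of 35 members at a positive log2 fold change and a median of 0.82. Camera called the cell cycle list (adjusted p = 5.3e-09; adjusted p = 0.61 with an estimated correlation), with 0 members past edgeR's threshold over all genes and 0 when adjusted over the list alone, and DESeq2 called 2 members higher. Mcm6 and Mcm2, subunits of the helicase that opens replication origins, were at 29.5 ± 7.53 and 22.6 ± 7.65 CPM in wild type and at 52.0 ± 9.18 and 44.7 ± 6.25 CPM in NICcA (adjusted p = 0.29 and 0.30). The wild type libraries differed among themselves, with list medians of 0.74, 0.041 and -0.81 on the log2 scale in replicates 1, 2 and 3 against 1.0 and 0.92 in NICcA replicates 2 and 3.

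Glycolysis and cholesterol biosynthesis genes had median log2 fold changes of 0.36 over 22 members and 0.41 over 24, carried mostly by NICcA replicate 2. The glycolysis medians were 0.50 and 0.14 on the log2 scale in NICcA replicates 2 and 3 and 0.016, 0.073 and -0.15 in wild type replicates 1, 2 and 3. Those of cholesterol biosynthesis were 0.68 in NICcA replicate 2 and 0.10 in NICcA replicate 3, which lay below wild type replicates 1 (0.30) and 2 (0.14) and above wild type replicate 3 (-0.44). Camera gave an adjusted p of 0.022 for glycolysis (adjusted p = 0.82 with an estimated correlation) and 0.019 for cholesterol biosynthesis (adjusted p = 0.82 with an estimated correlation). Hk1, a hexokinase, and Srebf2, the activator of cholesterol synthesis, had log2 fold changes of 0.46 (SE 0.14, adjusted p = 0.30) and 0.67 (SE 0.18, adjusted p = 0.28). Pfkfb4, a regulator of glycolytic flux, was at 79.6 ± 3.74 CPM in wild type and 53.3 ± 1.08 CPM in NICcA (log2 fold change -0.58, SE 0.10, adjusted p = 0.27). Fdft1, the squalene synthase, also had a negative value (log2 fold change -0.64, SE 0.18, adjusted p = 0.29). Gapdh, a glycolytic enzyme often used as a reference, had a log2 fold change of 0.44 (SE 0.18, adjusted p = 0.35) and Actb, which encodes beta-actin, one of 0.35 (SE 0.16, adjusted p = 0.36). Over all genes 0 members of either list passed with edgeR, while DESeq2 called 1 glycolysis gene lower and 1 cholesterol gene higher and 1 lower. Pfkfb4 was lower when adjusted over the list alone, and 0 cholesterol genes passed there.

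The glycolysis call ended without wild type replicate 1 (0.059), wild type replicate 3 (0.065) or NICcA replicate 2 (0.71), and the cholesterol call without wild type replicate 3 (0.3) or NICcA replicate 2 (0.79). Genes of the tricarboxylic acid cycle and respiratory chain did not stand apart (camera adjusted p = 0.26, median log2 fold change 0.08, 0 of 31 members over all genes with edgeR or DESeq2 and 0 when adjusted over the list alone). Without wild type replicate 2 or NICcA replicate 3 this list passed upward (0.025 and 0.04). Fh1 and Ndufs1 had log2 fold changes of 0.48 (SE 0.16, adjusted p = 0.32) and -0.15 (SE 0.09, adjusted p = 0.45). Hypoxia response genes did not stand apart either (camera adjusted p = 0.15, median log2 fold change 0.18, 0 of 17 over all genes with edgeR, 2 higher and 1 lower with DESeq2). Ddit4, an inhibitor of mTORC1, was at 1.94 ± 0.947 and 8.20 ± 1.15 CPM, and Bnip3l, a mitophagy receptor, at 152 ± 18.4 and 93.2 ± 12.1 CPM (both adjusted p = 0.27). Ddit4 and Ndrg1 were higher and Bnip3l was lower when adjusted over the list alone.

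Matrix remodelling and angiogenic factors held Mmp9, the 1 member of 24 that edgeR called over all genes, where DESeq2 called 2 higher and 4 lower, and did not stand apart as a list (camera adjusted p = 0.52, median log2 fold change -0.06 and mean 0.05). When adjusted over the list alone, Mmp9, Mmp13, Vegfc and Plau were higher and Mmp19, Hgf, Timp2, Igf1 and Fn1 were lower. Osteoclast genes share Mmp9 and Atp6v0d2 with other lists and did not stand apart (camera adjusted p = 0.93, median log2 fold change 0.08, 1 of 12 members higher over all genes with edgeR, 2 higher and 1 lower with DESeq2). Mmp9 and Ocstamp were higher and Atp6v0d2 and Ctsk were lower when adjusted over the list alone.

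Markers of other cell types that a marrow culture can hold were measured beside macrophage identity genes. Dendritic cell markers stood higher in NICcA as a group, with a median log2 fold change of 1.13 over 17 members. The list passed camera (adjusted p = 0.0013; adjusted p = 0.55 with an estimated correlation), with 0 members past edgeR's threshold over all genes and 0 when adjusted over the list alone, and DESeq2 called 1 higher. Zbtb46, a transcription factor of conventional dendritic cells, was at 4.27 ± 1.41 CPM in wild type and 9.17 ± 2.20 CPM in NICcA (log2 fold change 1.1, SE 0.32, adjusted p = 0.29), and Siglech, a marker of plasmacytoid ones, was at 0.105 ± 0.060 and 0.488 ± 0.310 CPM (adjusted p = 0.30). The list medians were 1.4 and 0.79 on the log2 scale in NICcA replicates 2 and 3 and -0.05, 0.29 and -0.49 in the wild type libraries.

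Haematopoietic progenitor genes stood higher as a group, with a median log2 fold change of 1.0 over 12 members (camera adjusted p = 0.0048; adjusted p = 0.55 with an estimated correlation). Myb, needed by blood progenitors, was at 0.811 ± 0.314 and 2.16 ± 0.543 CPM (adjusted p = 0.29), and Gfi1 was at 0.275 ± 0.0147 and 0.943 ± 0.570 CPM (adjusted p = 0.28). Neutrophil genes had a median of 0.56 over 18 members (camera adjusted p = 0.0055; adjusted p = 0.61 with an estimated correlation). Ngp, a neutrophil granule protein, was at 16.8 ± 4.10 and 29.7 ± 3.01 CPM (adjusted p = 0.28) and Cebpe, a factor of granule formation, at 3.24 ± 2.06 and 8.19 ± 1.53 CPM (adjusted p = 0.33). T and natural killer cell genes had a median of 0.63 over 12 members (camera adjusted p = 0.014; adjusted p = 0.55 with an estimated correlation). Their levels were low, with Il2rb at 0.0857 ± 0.056 and 0.281 ± 0.0253 CPM (adjusted p = 0.34), while Cd28 was at 18.7 ± 4.91 and 10.9 ± 3.21 CPM (adjusted p = 0.33). In each of these 3 lists 0 members passed over all genes with edgeR and 0 when adjusted over the list alone, while DESeq2 called 1 neutrophil gene higher and none of the others. Without NICcA replicate 3 the neutrophil call ended (0.13), as did that of T and natural killer cells (0.077), which also ended without both libraries numbered 3 (0.064).

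Macrophage identity genes did not stand apart (camera adjusted p = 0.27, median log2 fold change -0.06, 0 of 21 members over all genes with edgeR and 0 when adjusted over the list alone, 1 higher and 1 lower with DESeq2). Mpeg1, a pore-forming protein of macrophages, was at 3550 ± 728 and 2000 ± 177 CPM (adjusted p = 0.28), Fcgr1, an antibody receptor, at 57.8 ± 8.25 and 109 ± 44.5 CPM (adjusted p = 0.29), and Lyz2, the macrophage lysozyme, at 14400 ± 3000 and 9860 ± 784 CPM (log2 fold change -0.55, SE 0.23, adjusted p = 0.34). Monocyte genes did not stand apart (camera adjusted p = 0.73, median log2 fold change 0.20, 0 of 12 over all genes with edgeR, 1 higher and 1 lower with DESeq2), although when adjusted over the list alone Plac8 was higher and Chi3l3 lower. Plac8 was at 0.764 ± 0.0483 and 2.58 ± 0.963 CPM (adjusted p = 0.27).

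Mast cell, basophil and eosinophil genes had a median log2 fold change of 1.58 and a camera adjusted p of 0.10, with 0 of 14 members past edgeR's threshold over all genes, and DESeq2 called 1 higher and 2 lower. Ear2 and Ear1, eosinophil-associated ribonucleases of a family whose members can share reads, were at 1110 ± 146 and 8.36 ± 2.52 CPM in wild type and 476 ± 103 and 2.99 ± 0.612 CPM in NICcA (both adjusted p = 0.27), and both were lower when adjusted over the list alone. The list passed upward without wild type replicate 1 (0.032). Erythroid and megakaryocyte genes had a camera adjusted p of 0.15 (median log2 fold change 0.50, 0 of 10 over all genes with edgeR, 1 higher with DESeq2), with Itga2b, the platelet integrin alpha chain, at 3.55 ± 0.778 and 8.62 ± 0.718 CPM (adjusted p = 0.27) and higher when adjusted over the list alone. The haemoglobin gene Hbb-b2, whose counts were identical to those of Hbb-bt, was at 0.141 ± 0.132 and 0.904 ± 0.456 CPM (adjusted p = 0.33). Without wild type replicate 3 (0.014) or without both libraries numbered 3 (0.0037) that list passed upward.

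B cell genes (camera adjusted p = 0.93, median log2 fold change -0.14 and mean 0.16, 0 of 5 over all genes with edgeR or DESeq2) and stromal and endothelial genes (camera adjusted p = 0.67, median log2 fold change -0.40, 0 of 11 with edgeR, 1 lower with DESeq2) did not stand apart, and 0 members of either passed when adjusted over the list alone. Blk and Fcrla had log2 fold changes of 1.84 (SE 0.92, adjusted p = 0.39) and -0.63 (SE 0.44, adjusted p = 0.52). Postn and Cdh5 had log2 fold changes of -2.06 (SE 0.65, adjusted p = 0.31) and -1.21 (SE 0.45, adjusted p = 0.33).

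Immediate early and heat shock genes, which respond to handling, did not stand apart (camera adjusted p = 0.75, median log2 fold change 0.19, 0 of 21 over all genes with edgeR, 1 lower with DESeq2), and Fos alone was lower when adjusted over the list alone. Nr4a1 had a log2 fold change of 1.14 (SE 0.35, adjusted p = 0.30). Genes of endoplasmic reticulum stress and the amino acid response did not stand apart (camera adjusted p = 0.93, median log2 fold change -0.03 and mean 0.20, 0 of 21 over all genes with edgeR, 2 higher and 3 lower with DESeq2). When adjusted over the list alone, Sesn2, Asns, Psat1 and Chac1 were higher and the chaperone genes Hspa5, Hsp90b1 and Dnajb9 were lower. Hspa5, the main chaperone of the endoplasmic reticulum, was at 1190 ± 90.0 and 840 ± 28.6 CPM and Dnajb9 at 30.5 ± 2.49 and 20 ± 3.2 CPM (both adjusted p = 0.28). The Y-linked genes Uty and Ddx3y were expressed in all 5 libraries, at 23.7 to 33.8 and 40.8 to 79.4 CPM, with adjusted p values of 0.36 and 0.41, and 0 of the 4 measured sex-linked genes passed over all genes with edgeR or DESeq2 or, with edgeR, when adjusted over the list alone.

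**Figure D2:**
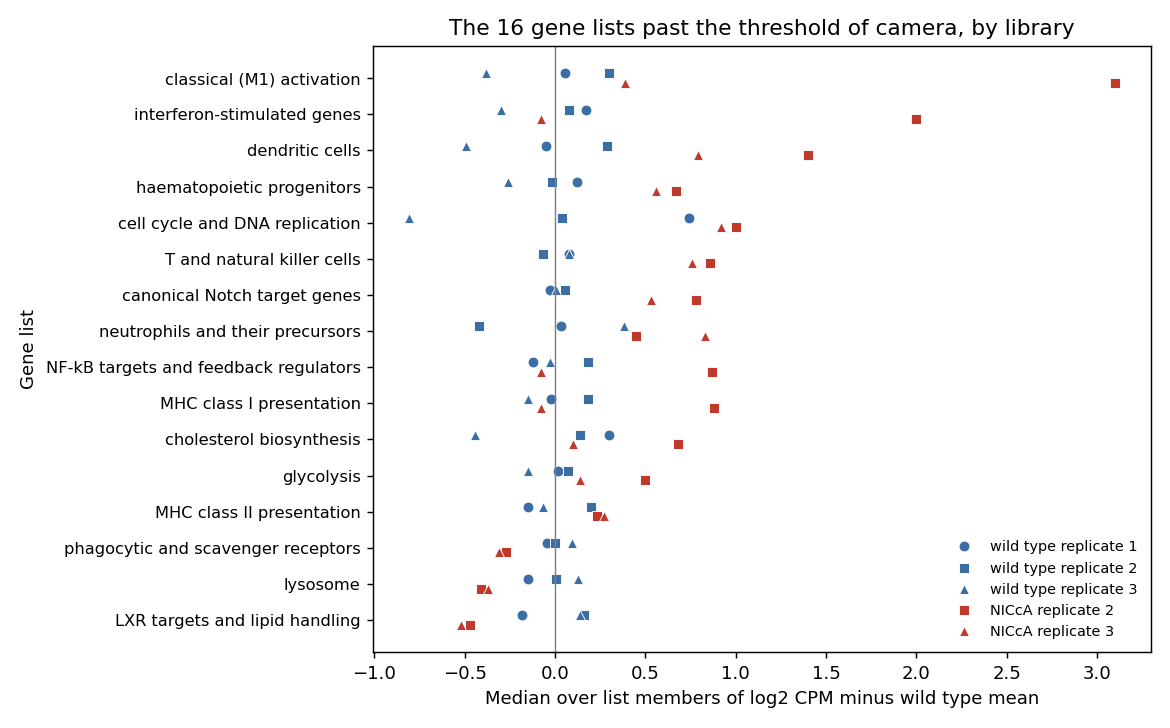
For each of the 16 gene lists past the threshold of camera with its preset correlation, the median over list members of the log2 CPM minus the wild type mean; points are libraries, with wild type in blue and NICcA in red. Interferon-stimulated genes sit at 2.0 in NICcA replicate 2 and at -0.078 in NICcA replicate 3, while lysosomal genes sit at -0.41 and -0.37 in the NICcA libraries.

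In total 16 of 31 lists passed camera with the preset correlation, 13 upward and 3 downward. With an estimated correlation 0 lists passed, and 0 passed fry's test of a common direction, while 15 of the 31 passed its test of change in either direction. Among the 16 lists the estimated correlation ran from -0.061 (T and natural killer cells) to 0.94 (interferon-stimulated genes). It lay below the preset 0.01 also for canonical Notch target genes (-0.015) and haematopoietic progenitors (-0.043), and above it for the others. For the lists below it, correlation between members does not account for the lost call. It was 0.87 for cell cycle genes, 0.81 for classical activation and 0.32 for lysosomal genes, far above the preset. For such lists the effects of correlation and of the fewer degrees of freedom were not told apart. For each of the 16 lists, no other alternative gave a higher adjusted p than the estimated correlation did. The model behind these tests pools the spread within both genotypes, over 3 wild type and 2 NICcA libraries. With the preset correlation, camera weighs a list against the spread across genes. The lists of activation genes above show how far the 2 NICcA libraries lay apart.

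The second deposited table adds noncoding RefSeq transcripts and FANTOM cDNA clones, and the question there is whether any of these differ. The clones were not sorted into coding and noncoding. Only Apol7c and Mmp9 passed the threshold in that table, with 22619 transcripts tested by limma on log2(RPKM + 1), a scale that understates the change of low transcripts. Rows in both tables hold nearly the same RPKM values, so these calls are not separate evidence. Adamdec1 was at 0.0322 RPKM in wild type and 3.28 in NICcA (limma adjusted p = 0.064). Mpzl2 was at 0.113 and 2.40 RPKM (limma adjusted p = 0.16). Apol7c rose from 1.33 ± 0.299 to 26.7 ± 1.97 RPKM (log2 fold change 3.58, SE 0.14, adjusted p = 0.0024) and Mmp9 from 0.255 ± 0.0625 to 5.89 ± 0.306 RPKM (log2 fold change 2.46, SE 0.10, adjusted p = 0.0025). Both are protein-coding and also in the count table. Among 889 noncoding RefSeq transcripts and 7649 full-length cDNA clones of the FANTOM collection, 0 passed limma's test (smallest adjusted p = 0.23), and 117 and 892 had an unadjusted p below 0.05. Without NICcA replicate 2 limma called 0 transcripts in this table, without NICcA replicate 3 it called 44, and without wild type replicate 2 it called 1.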

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

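The edgeR option legacy = TRUE, listed as an alternative before the data were examined, is the default of the installed version and so is the setting reported. The setting legacy = FALSE, 1 row per gene and the fit without both libraries numbered 3 were chosen after seeing the data. The 4 genes changed, all of them by at least 2-fold, kept their number and identity with RLE factors, upper-quartile scaling and 1 row per gene. Scaling by totals alone gave 5 genes and shifted the median gene by 0.11 on the log2 scale, as did log2(RPKM + 0.1), so values under either are relative to that shift. No low-count filter gave 11 genes (10 higher, 1 lower), at least 5 CPM gave 2, limma-voom 2, log2(RPKM + 1) 2, log2(RPKM + 0.1) 2, unfiltered RPKM 3 (2 by at least 2-fold), legacy = FALSE 8 and the fit without both libraries numbered 3 gave 161 (148 higher, 13 lower). DESeq2 gave 527 genes, 212 of them by at least 2-fold, and left the adjusted p of 276 genes unset. Leaving out 1 library gave 0 to 44 genes, where a lone NICcA library is assumed to vary like the wild type ones. The cause of these differences was not tested.

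No label pairs the libraries beyond the replicate number, which gives 2 pairs, whose deviations correlated at 0.21 and 0.17 across genes. With 2 NICcA libraries, 1 deviation mirrors the other, so these values are not separate. The difference of NICcA replicates 2 and 3 correlated at 0.21 with that of wild type replicates 2 and 3. With that of wild type replicates 1 and 3 it correlated at 0.1. Both libraries numbered 3 had fewer genes at a count of 0 (2364 and 3260) than the others (4951 to 5254). Whether the number marks shared handling was not tested. With the replicate number as a block, 0 genes were called, at 0 by 2-fold, while 15 lists and 2 transcripts of the second table were. Wild type replicate 1 has no partner in that fit, which leaves few degrees of freedom. The log2 fold changes stayed large, at 6.71 for Adamdec1, 4.07 for Apol7c, 4.31 for Mmp9 and 4.42 for Mpzl2 (edgeR adjusted p = 0.095 for each). The block ended the list calls on MHC class II (0.13) and phagocytic receptors (0.051) and added one on mast cell, basophil and eosinophil genes (0.0037).

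The 16 lists became 0 with an estimated correlation, 0 with fry, 16 with RLE scaling or a prior count of 0.5, 15 at 1 CPM, and 10 to 17 with 1 library left out. Without NICcA replicate 2 the direction turned for interferon-stimulated genes (adjusted p = 0.14), NF-kB targets (0.37) and MHC class I (0.82), whose lowest values with 1 library left out were 3.8e-27, 5.7e-09 and 3.9e-05, each without NICcA replicate 3. The 2 transcripts of the second table became 0 to 44 with 1 library left out. Of 1505 values of 75 named genes, 1405 kept their direction and side of the threshold, 23 lost their call, 77 gained one and 0 reversed. Of 369 values of 31 lists, the numbers were 309, 51, 6 and 3.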

Other observations

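The tests below on sequencing depth, on scaling and dendritic cells in NICcA replicate 2, on gene families on X in NICcA replicate 3 and on other splits of the libraries were chosen only after the result was seen; those on genomic DNA, on gene families on X in wild type replicate 3 and on a state that differs between cultures were written before. Of the 10 splits of the 5 libraries into 3 and 2, 1, the real one, gave 4 genes, and the highest of the others gave 1, but 10 splits are too few for a share under 0.05.

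The noncoding transcript Gt(ROSA)26Sor, made from a locus widely used for inserting conditional cassettes in mice, was at 6.06 ± 0.891 RPKM in wild type and 2.34 ± 0.468 RPKM in NICcA (row NR_027009; log2 fold change of RPKM + 1 -1.08, SE 0.15, limma adjusted p = 0.23), and it was chosen after its values were seen. Its row NR_027008 was at 5.57 ± 0.804 and 2.16 ± 0.441 RPKM, and its row NR_027010 was at 5.09, 4.27 and 5.67 RPKM in wild type and 3.88 and 3.79 RPKM in NICcA. The neighbouring genes Thumpd3 and Setd5 had edgeR log2 fold changes of -0.01 (SE 0.11) and -0.27 (SE 0.12, adjusted p = 0.36). Gt(ROSA)26Sor overlaps the end of Thumpd3 on the opposite strand in the GENCODE annotation, so their reads cannot be fully told apart without strand. The labels do not say where the NICcA allele lies, no explanation was tested, and the difference did not pass the adjustment.

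Interferon-stimulated genes were high in NICcA replicate 2 alone, with a list median of 2.0 on the log2 scale there, -0.078 in NICcA replicate 3 and -0.30 to 0.17 in wild type. Library scaling is argued against by macrophage identity genes, whose median difference between NICcA replicates 2 and 3 was -0.02 on the log2 scale of CPM + 0.1, where that of interferon-stimulated genes was 2.38. A larger number of dendritic cells in that culture stays open: 16 of their markers outside the interferon list had a median difference of 0.42 with quartiles at -0.07 and 0.90. The genotype, and an activation of that single culture or its animal, were not tested and stay open.

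Cell cycle genes ordered all 5 libraries, from NICcA replicate 2 down to wild type replicate 3. A state that differs between cultures of a genotype is a candidate explanation. Over 11258 genes at a mean of at least 1 CPM, wild type replicate 1 minus replicate 3 correlated with NICcA minus wild type replicate 2 at r = 0.60. The 2 differences have no library in common, but the first principal component already held the libraries in the same order. The correlation thus restates that the wild type libraries differ along the axis that separates NICcA from them. It cannot tell a culture state from the genotype. Genes are not independent replicates, and the genotype, as part or whole of the cell cycle order, was not tested and stays open. The axis runs over all genes, so other lists may follow it too, such as lysosomal genes, whose medians fell from wild type replicate 3 (0.13) over replicates 2 (0.0065) and 1 (-0.15) to NICcA replicates 3 (-0.37) and 2 (-0.41).

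Wild type replicate 3 and NICcA replicate 3 had fewer genes at a count of 0 than the other libraries, and depth is argued against, since after thinning to the smallest library wild type replicate 2 still had 2.16 times as many genes at 0 as wild type replicate 3. Traces of genomic DNA are a candidate source: among 3552 genes at 0 in the other 3 libraries, counts per unit length in wild type replicate 3 were 0.44 times as high on X as on autosomes (95% bootstrap interval 0.34 to 0.55), near the ratio of male DNA, and 0.53 times (0.39 to 0.71) in NICcA replicate 3. With these genes in 4 classes by length, the mean count in wild type replicate 3 was 0.89 in the shortest class and 3.0 in the longest. Reads from RNA can also rise with transcript length, and a single X can lower stray RNA as well as DNA. Neither result therefore tells genomic DNA from stray RNA. Among genes with at least 95% of their 31-base words found in no other GENCODE gene the ratio was 0.49 (0.37 to 0.63) in wild type replicate 3, which argues against multi-copy gene families on X as its whole cause there, and 0.55 (0.36 to 0.77) in NICcA replicate 3, where they stay open since the interval reaches past the bound of 0.7 set for the former; copies outside annotated transcripts were not covered. Genes with few counts in these libraries may carry such counts. Dtx1, at counts of 4, 4 and 22 in wild type replicates 1, 2 and 3, lay in replicate 3 well above the mean of 3.0 in the longest class. It was at 25 and 14 in NICcA replicates 2 and 3.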
